A study of Homo sapiens with 12 samples.

How the data were processed

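RNA was sequenced from 4 human breast epithelial cell lines of the MCF10 series: MCF10A, a non-tumorigenic immortalised line, and 3 lines derived from it, MCF10AT1, MCF10DCIS and MCF10CA1a. Per the labels, each line was sampled in 3 libraries, 12 in all, made from total RNA with a stranded kit, and all lines were grown in the same medium with horse serum, insulin, EGF, cholera toxin and hydrocortisone. Per the submitters' processing notes, STAR and edgeR were among the tools used and the genome build was hg38; their versions, the quantification program, the gene annotation and the strand setting are not given in the sources used here.

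The authors deposited 1 table of TPM with 1 column per line, the authors' mean over that line's libraries, for 59427 gene symbols. All deposited values (100%) had the form of a mean of 3 numbers with 6 decimals, within a tolerance of 0.01 of the step between such means, and 33.0% of the values above 0 were themselves numbers with 6 decimals. Each column summed to 1000000 TPM. No per-library values were used here, so there is no replicate check: no difference has an SD, a standard error or a p-value, and the number of libraries behind a mean enters no calculation. The depth is unknown, because TPM keeps no count of reads, and no counting interval or detection floor is given. The tests fixed before the data were examined (limma on log2(TPM + 1) with 12 libraries) needed values per library and could not be run. The comparisons below are descriptive and use a fixed rule of size in their place.

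Differences were computed as log2(TPM + 1) of the first-named line minus that of the second, so a difference of low genes is understated. Of the 59427 symbols, 26189 were at 0 in all lines, and the 13108 with a mean TPM of at least 1 in at least 1 of the 4 lines entered the comparisons. A gene was counted as higher or lower when its log2 difference was at least 1, which is a 2-fold difference of TPM + 1. All 6 pairs of lines were compared. For genes counted in all 3 derived lines, the number that independent lists of these sizes would share is given. The order MCF10A, MCF10AT1, MCF10DCIS, MCF10CA1a was examined by counting genes with a difference in 1 direction of at least 0.25 at each step and at least 1 in total, and the same count was made for the 11 other orders of the 4 lines.

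A set of 31 gene lists with 739 entries, 601 of them among the 13108 genes, was fixed before the data were examined. For the 27 lists with at least 5 such genes, the median log2 difference was placed among those of 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean expression. A list is said to stand above or below the matched random lists when its percentile was at least 97.5 or at most 2.5. The filter, the size of a step and the percentile limits were set once the table was known to hold means. The percentiles describe the deposited means and are not p-values, and a list's direction relative to matched genes can differ from the sign of its median where the whole set of genes is displaced.

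Named genes followed a rule fixed before the data were examined. HRAS, CDH1, VIM, KRT5, KRT14 and TP63 are given in every comparison. To these were added the 6 higher and 6 lower genes with the largest differences and at least 10 TPM in the higher line (4 and 4 for pairs without MCF10A). For each list with at least 3 genes past the rule of size, the 2 members with the largest difference in the direction most members took could be named too. Of the genes going through every step, the 5 with the largest total difference in each direction are named. Uncharacterised loci, small RNAs, antisense transcripts, pseudogenes and genes that mark sex were left out of the part on largest differences. The rule's condition that the libraries of the lines do not overlap could not be applied to means. Positions are from GENCODE release 29 on GRCh38, the build that hg38 denotes; 54529 of the 59427 symbols were found in it.

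Structural and small non-coding RNAs took most of the TPM in each line, so a gene's TPM also depends on them. Of the alternatives listed before the data were examined, 6 could be run: a pseudocount of 0.1, no filter on low values, a filter of 5 TPM, quantile normalization, median-of-ratios scaling, and TPM rescaled to 1000000 after leaving out mitochondrially encoded, ribosomal protein and structural or small non-coding RNAs (called rescaled TPM). Leaving out each library, a replicate block, other limma settings and other tests of gene lists could not be run on means.

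The calculation was tested on simulated tables. The simulated lines were copies of the MCF10A column with set changes, and noise was added only for the gene lists. In a simulated comparison of MCF10AT1 against MCF10A over 12045 genes, the rule of size recovered 50 of 50 genes raised 4-fold and 50 of 50 raised 8-fold. It recovered 43 of 50 lowered to 0.25 and 48 of 50 lowered to 0.125 of their level. It counted 0 unchanged genes, which the lack of noise fixed in advance, so false counts between real means were not measured. With noise, 4 of 100 lists of unchanged genes lay outside the percentile limits. These lists were random draws with independent noise, so a share near that set by the limits was built in. How often lists of genes that vary together pass the limits was not measured. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.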

Results

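Bulk RNA-seq was used to compare gene expression across 4 lines of the MCF10 breast epithelial series, which serve as a model of breast cancer progression. MCF10A is a non-tumorigenic line, MCF10AT1 was obtained from it by transformation with an activated HRAS, MCF10DCIS is used as a model of ductal carcinoma in situ, and MCF10CA1a is a metastatic line. The labels state 3 libraries per line. The values analysed were the authors' mean TPM per line, so none of them has an error and no difference between lines could be set against the spread between libraries. The depth of the libraries is unknown. At least 1 TPM was reached by 12045 genes in MCF10A, 11894 in MCF10AT1, 11444 in MCF10DCIS and 11977 in MCF10CA1a.

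Structural and small non-coding RNAs, among them the signal recognition particle RNA RN7SL1 and the transcriptional regulator RN7SK, held most of the TPM. Their share was 57.6% in MCF10A, 59.9% in MCF10AT1, 66.0% in MCF10DCIS and 59.8% in MCF10CA1a. RN7SL1 alone held 29.7% in MCF10A and 41.8% in MCF10DCIS. Ribosomal protein genes held 6.95%, 7.71%, 6.69% and 8.13% in the same order of lines, and mitochondrially encoded genes 1.01%, 0.858%, 0.675% and 0.910%. All remaining genes shared 34.4% of the TPM in MCF10A, 31.5% in MCF10AT1, 26.7% in MCF10DCIS and 31.1% in MCF10CA1a. With the TPM as deposited, the median log2 difference of all 13108 genes against MCF10A was -0.066 in MCF10AT1, -0.38 in MCF10DCIS and -0.074 in MCF10CA1a. After rescaling without these RNA classes it was 0.040, -0.094 and 0.046. The total counts of each pair are therefore given on both scales, counts within gene lists are those of the deposited TPM unless stated, and single differences of MCF10DCIS are to be read against its median of -0.38.

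HRAS, the small GTPase introduced in activated form into MCF10AT1, was examined first because it bears on the line labels. Its mean TPM was 50.8 in MCF10A, 126 in MCF10AT1, 276 in MCF10DCIS and 312 in MCF10CA1a. The log2 differences from MCF10A were 1.29, 2.42 and 2.59, above the rule of size in all 3 derived lines. HRAS was higher in MCF10DCIS than in MCF10AT1 by 1.13 log2 units. Between MCF10CA1a and MCF10DCIS it differed by 0.17, and the sign of that difference was not kept under 3 other scalings, where it was -0.051, -0.083 and -0.19. The gene lies on chromosome 11 from 532242 to 537287 on the minus strand (GRCh38), and reads of the endogenous and of the introduced gene are not told apart in the table.

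**Figure D1:**
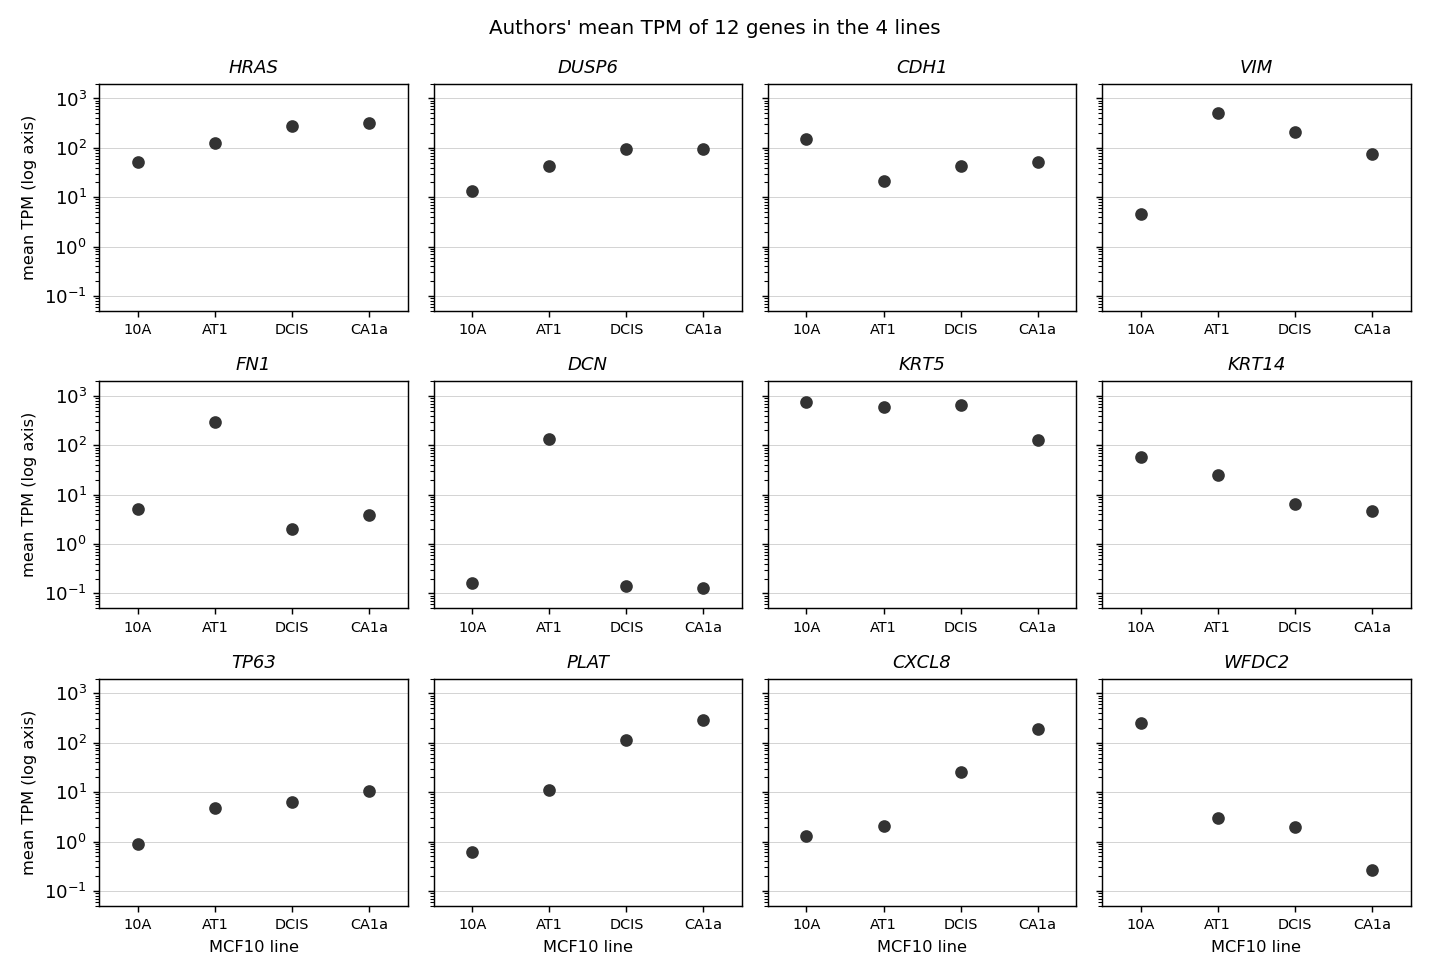
Authors' mean TPM (log axis) of 12 genes in MCF10A, MCF10AT1, MCF10DCIS and MCF10CA1a, 1 point per line and no error bars because only means were analysed. HRAS was 50.8 TPM in MCF10A and 312 TPM in MCF10CA1a, and DCN was 134 TPM in MCF10AT1 and below 1 TPM in the other lines.

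MCF10AT1 was compared with MCF10A, the line from which it was obtained by HRAS transformation. With 1 line per stage, effects of HRAS cannot be separated from other differences between these lines, such as the displaced chromosomes described below. Mesenchymal genes were higher and epithelial genes lower in MCF10AT1. Of 16 measured mesenchymal genes, 12 were higher and 0 lower by the rule of size, with a median log2 difference of 1.87 that stood above all 10000 matched random lists. The intermediate filament gene VIM was 4.56 TPM in MCF10A and 516 TPM in MCF10AT1, the proteoglycan gene DCN 0.163 and 134 TPM, and the fibronectin gene FN1 5.03 and 303 TPM. Of 24 epithelial junction genes and regulators, 22 were lower and 0 higher, with a median of -1.92, below all matched random lists. E-cadherin (CDH1) was 149 TPM in MCF10A and 21.3 TPM in MCF10AT1, the epithelial transcription factor gene ELF3 222 and 10.9 TPM, and the serine protease gene PRSS8 75.9 and 4.98 TPM. Of the lists for other cell types, 4 of 12 fibroblast markers reached 1 TPM in any line, and the fibrillar collagen genes COL1A1, COL1A2 and COL3A1 were at 3.22, 0.0408 and 0.0491 TPM in MCF10AT1. CDH1 lies on chromosome 16 from 68737225 to 68835548 and VIM on chromosome 10 from 17228259 to 17237593 (GRCh38).

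In the same comparison 7 of 11 luminal genes were lower and 0 higher (median -1.14, percentile 0.01), among them CD24 with 299 TPM in MCF10A and 24.3 TPM in MCF10AT1 and AGR2 with 12.5 and 0.317 TPM. The epidermal differentiation list had 6 of 17 genes lower and 0 higher (median -0.47, percentile 0.36), with the kallikrein protease genes KLK7 at 223 and 8.27 TPM and KLK5 at 953 and 55.4 TPM. The RAS/ERK output list stood above matched lists (median 0.44, percentile 100) with 4 of 22 genes higher and 3 lower, or 7 and 2 with rescaled TPM. The ERK phosphatase gene DUSP6 was 13.4 TPM in MCF10A and 42.4 TPM in MCF10AT1, and the feedback inhibitor gene SPRY4 1.73 and 6.53 TPM. Matrix proteases and inhibitors (6 of 16 higher, 1 lower, median 0.73) and collagens, laminins and matricellular proteins (8 of 18 higher, 0 lower, median 0.75) both stood at percentile 100. TIMP1, an inhibitor of matrix metalloproteinases, was 86.3 and 504 TPM, and the collagen gene COL12A1 1.11 and 17.9 TPM. The inflammatory list had 2 of 23 genes higher and 7 lower, with a median of 0.059 and a mean of -0.42 (percentile 90.2), or 4 higher and a median of 0.18 with rescaled TPM. Basal and myoepithelial genes had 2 of 19 higher and 4 lower, with a median of 0.15 and a mean of -0.18 (percentile 97.1). They stood above matched lists only with rescaled TPM, with 3 higher and 3 lower and a median of 0.28 (percentile 98.5). The complement gene C3 was 202 TPM in MCF10A and 25.6 TPM in MCF10AT1, and the keratin gene KRT15 2830.4 and 395 TPM. Antigen presentation genes stood below matched lists (median -0.38, percentile 0.73) with 0 of 16 past the rule of size. Mitochondrially encoded genes stood below (median -0.36, percentile 0.56) and ribosomal protein genes and replication-dependent histone genes above (medians 0.19 and 0.14, percentiles 99.1 and 98.8), with 0 members of any of the 3 lists past the rule of size.

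Among single genes, the largest differences upward from MCF10A to MCF10AT1 were those of DCN (6.86), VIM (6.54), FN1 (5.66), IGFBP7 (5.28), the aldehyde dehydrogenase gene ALDH3A1 (4.52) and the receptor phosphatase gene PTPRS (3.91). The largest downward were those of CYBA (-7.04), which encodes a subunit of NADPH oxidases, AZGP1 (-6.18), WFDC2 (-5.97), NCCRP1 (-5.57), KLK8 (-5.39) and RARRES1 (-5.36). CYBA was 149 TPM in MCF10A and 0.140 TPM in MCF10AT1. Of the basal keratin genes, KRT5 was 768 and 592 TPM (log2 difference -0.37) and KRT14 57.8 and 24.6 TPM (-1.20). TP63, a transcription factor of basal epithelium, was 0.901 and 4.81 TPM (1.61). In all, 444 genes were higher and 770 lower in MCF10AT1, which puts 36.6% of the counted genes on the higher side; with rescaled TPM the counts were 749 and 859 and the share 46.6%. Of the 27 lists, 6 stood above and 5 below matched random lists.

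**Figure D2:**
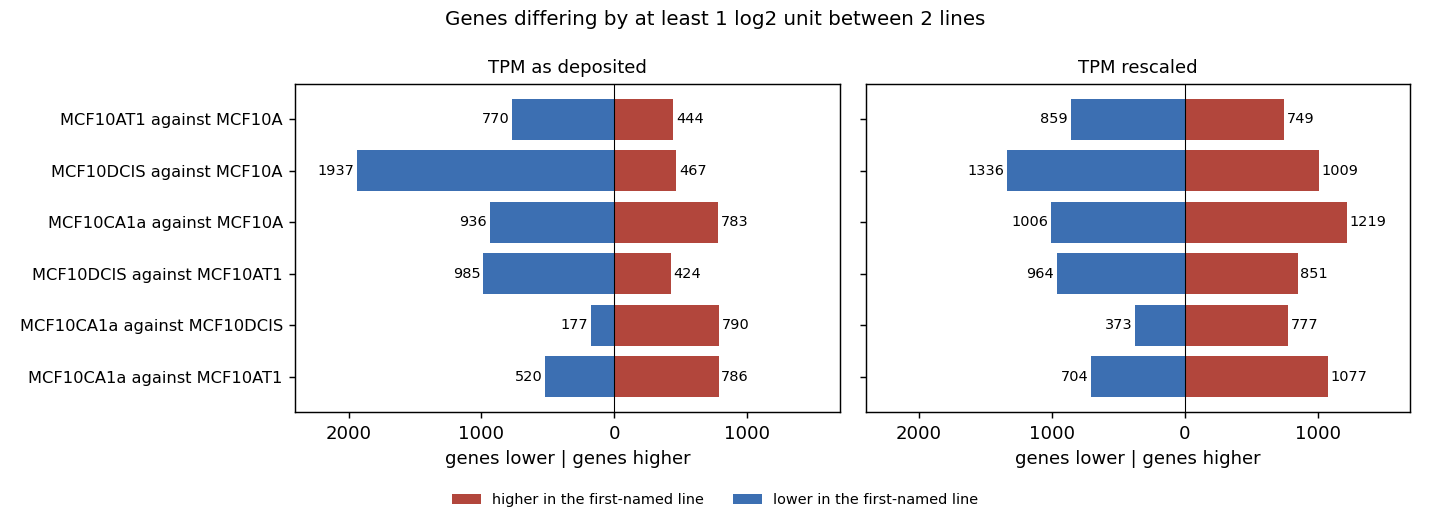
Numbers of genes lower (blue, left) and higher (red, right) by at least 1 log2 unit in the first-named line of each of the 6 pairs, with TPM as deposited and with TPM rescaled without structural, mitochondrial and ribosomal protein RNAs. Against MCF10A, MCF10DCIS had 467 genes higher and 1937 lower as deposited, and 1009 and 1336 after rescaling.

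MCF10DCIS was compared with MCF10A to describe the ductal carcinoma in situ stage. RAS/ERK output genes were higher, with 11 of 22 past the rule of size, 0 lower and a median of 0.96 (percentile 100). DUSP6 was 13.4 TPM in MCF10A and 95.9 TPM in MCF10DCIS, and SPRY1 1.28 and 7.58 TPM. The inflammatory list (NF-kB targets and cytokines) had 9 of 23 genes higher, or 13 with rescaled TPM, and 2 lower (median 0.49, or 1.05 with rescaled TPM, percentile 100), with CXCL8 at 1.31 and 25.5 TPM and IL1A at 0.813 and 14.6 TPM. Basal and myoepithelial genes stood above matched lists (6 of 19 higher, 3 lower, median 0.32, or 0.87 with rescaled TPM, percentile 100), among them the nerve growth factor receptor gene NGFR at 0.162 and 32.6 TPM and the integrin gene ITGB4 at 72.9 and 563 TPM. Luminal genes had 6 of 11 lower and 0 higher (median -1.26, percentile 0.01), with CD24 at 299 and 8.27 TPM and MUC1 at 123 and 11.2 TPM. Epithelial junction genes had 12 of 24 lower, or 8 with rescaled TPM, and 1 higher (median -0.93, percentile 0.03), and CDH1 was 149 and 42.3 TPM.

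Genes of the cell cycle stood below matched lists in MCF10DCIS (10 of 34 lower, or 4 with rescaled TPM, 0 higher, median -0.68, percentile 0.54). CCNE2, a cyclin of the entry into S phase, was 8.23 TPM in MCF10A and 1.02 TPM in MCF10DCIS, and the transcription factor gene E2F1 11.5 and 2.11 TPM. Replication-dependent histone genes were lower too, with 19 of 35 past the rule of size, or 11 with rescaled TPM, 0 higher and a median of -1.03 (percentile 0). H2BC14 was 89.0 and 11.4 TPM. Near-identical histone copies share reads and their single values are uncertain, and their transcripts lack poly(A) tails, so their level also depends on how RNA was selected. With rescaled TPM the median was -0.36 for cell cycle genes and -0.67 for the histone genes, and both lists still stood below matched lists. Collagens, laminins and matricellular proteins stood above (3 of 18 higher and a median of 0.31, or 6 and 0.69 with rescaled TPM, 1 lower, percentile 100). The 16 mesenchymal genes went both ways, with 2 higher, 5 lower, a median of -0.17 and a mean of 0.23 (percentile 82.0), or 3 higher, 6 lower and a median of -0.32 (percentile 19.0) with rescaled TPM. VIM was 213 TPM in MCF10DCIS, while FN1 was 2.01 TPM, and the transcription factor gene TWIST1 was 19.6 TPM in MCF10A and 4.45 TPM in MCF10DCIS. Ribosomal protein genes had a median of -0.040, above matched lists (percentile 99.3), with 0 of 39 past the rule of size. The leukocyte marker list stood below (3 of 5 lower, median -1.31, percentile 0.37), with the actin regulator gene CORO1A at 37.0 and 2.81 TPM.

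The genes with the largest upward differences in MCF10DCIS were SPARC (6.29), the plasminogen activator gene PLAT (6.14), VIM (5.27), BST2 (5.21), NGFR (4.85) and FKBP10 (4.79). SPARC, which encodes a matricellular protein, was 0.203 TPM in MCF10A and 92.9 TPM in MCF10DCIS, and BST2, an interferon-inducible membrane protein, 0.831 and 67.0 TPM. The interferon-stimulated list had 3 of 26 genes higher and 6 lower (median -0.57, percentile 7.03), or 4 and 8 with rescaled TPM. The genes with the largest downward differences were KLK7 (-7.64), VSTM2L (-6.96), CYBA (-6.90), KLK8 (-6.41), WFDC2 (-6.40) and the mesothelin gene MSLN (-6.39). KRT14 was 6.62 TPM (-2.95) and TP63 6.22 TPM (1.92). KRT5 was 643 TPM, a difference of -0.26 that became 0.11 with rescaled TPM. In all, 467 genes were higher and 1937 lower, a higher side of 19.4%. With rescaled TPM the counts were 1009 and 1336 (43.0% higher), and with median-of-ratios scaling 846 and 845. Of the lists 5 stood above and 5 below, and 9 of these 10 did so with rescaled TPM, from which the remaining list, ribosomal proteins, is left out. Without a filter on low values, 3 lists stood below.

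MCF10CA1a was compared with MCF10A to describe the metastatic line. The inflammatory list differed most in its median, with 17 of 23 genes higher, 3 lower and a median of 1.65 (percentile 100). The interleukin gene IL1B was 0.382 TPM in MCF10A and 135 TPM in MCF10CA1a, and the chemokine gene CXCL8 1.31 and 188 TPM. RAS/ERK output genes had 13 of 22 higher and 0 lower (median 1.46, percentile 100), among them the EGF receptor ligand gene HBEGF at 4.20 and 58.0 TPM and SPRY1 at 1.28 and 15.4 TPM. Matrix proteases and inhibitors had 8 of 16 higher and 3 lower (median 0.95, percentile 100). PLAT was 0.619 and 294 TPM and the protease inhibitor gene SERPINB2 0.678 and 42.2 TPM. Interferon-stimulated genes stood above matched lists (7 of 26 higher and a median of 0.51, or 12 and 0.85 with rescaled TPM, 1 lower, percentile 100). BST2 was 0.831 and 83.2 TPM and IFITM1 0.233 and 22.9 TPM.

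The epidermal differentiation list went both ways in MCF10CA1a, with 9 of 17 genes higher and 5 lower and a median of 1.02 (percentile 100). KRT13, a keratin of stratified epithelia, was 0.401 TPM in MCF10A and 58.9 TPM in MCF10CA1a, whereas KLK7 was 223 and 0.172 TPM. Basal and myoepithelial genes had 6 of 19 higher and 3 lower (median 0.30, or 0.64 with rescaled TPM, percentile 99.7). YAP/TAZ targets had 4 of 18 higher and 1 lower (median 0.57, percentile 100). Collagens, laminins and matricellular proteins had 4 of 18 higher and a median of 0.28, or 6 and 0.43 with rescaled TPM, and 1 lower (percentile 99.2). The receptor kinase gene AXL, a YAP/TAZ target, was 9.18 and 76.7 TPM. TGF-beta targets had 1 of 16 higher and a median of 0.26, or 3 and 0.41 with rescaled TPM, and 1 lower (percentile 98.3). Cell cycle genes had a median of 0.13, or 0.28 with rescaled TPM (percentile 98.7 on both scales), with 0 of 34 higher, or 1 with rescaled TPM, and 1 lower. Cholesterol biosynthesis genes stood below matched lists (4 of 23 lower, or 2 with rescaled TPM, 0 higher, median -0.67, percentile 0), with the sterol demethylase gene CYP51A1 differing by -1.28 and MVD at 64.5 and 27.5 TPM. CYP51A1 lies on chromosome 7 and MVD on chromosome 16. As described below, genes of both chromosomes were lower as a whole in MCF10CA1a, with medians of -0.60 and -0.61 on the rescaled scale. On that scale CYP51A1 differed by -1.16 and MVD by -1.08. Luminal genes had 5 of 11 lower and 0 higher (median -0.61, percentile 0.12), with MUC1 at 123 and 0.438 TPM. Epithelial junction genes had 9 of 24 lower and 1 higher (median -0.34, or -0.21 with rescaled TPM, percentile 1.23). The 16 mesenchymal genes had 2 higher and 4 lower (median -0.27, below matched lists only with rescaled TPM, at percentile 1.48). The leukocyte marker list stood below (3 of 5 lower, 0 higher, median -1.55, percentile 0.06), with CD14 at 11.9 and 0.224 TPM.

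The largest upward differences of single genes in MCF10CA1a were those of PLAT (7.51), IL1B (6.62), the glutathione peroxidase gene GPX2 (6.43), CXCL8 (6.35), FKBP10 (5.94) and UGT1A6 (5.77). UGT1A6 shares exons with the other genes of its locus, and its value is uncertain for that reason. The largest downward were those of the linker histone gene H1-5 (-8.03), the hair keratin gene KRT81 (-7.89), WFDC2 (-7.65), KLK7 (-7.58), CYBA (-7.00) and VSTM2L (-6.94). H1-5 was 450 TPM in MCF10A and 0.731 TPM in MCF10CA1a. KRT81, which has close paralogs, was 2100.1 and 7.87 TPM. KRT5 was 126 TPM (-2.60), KRT14 4.75 TPM (-3.36), TP63 10.7 TPM (2.62), VIM 74.1 TPM (3.76) and CDH1 51.9 TPM (-1.51). In all, 783 genes were higher and 936 lower, or 1219 and 1006 with rescaled TPM. Of the lists, 10 stood above and 4 below matched random lists, and all 14 kept their direction with rescaled TPM. With a filter of 5 TPM, 2 lists stood below.

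**Figure D3:**
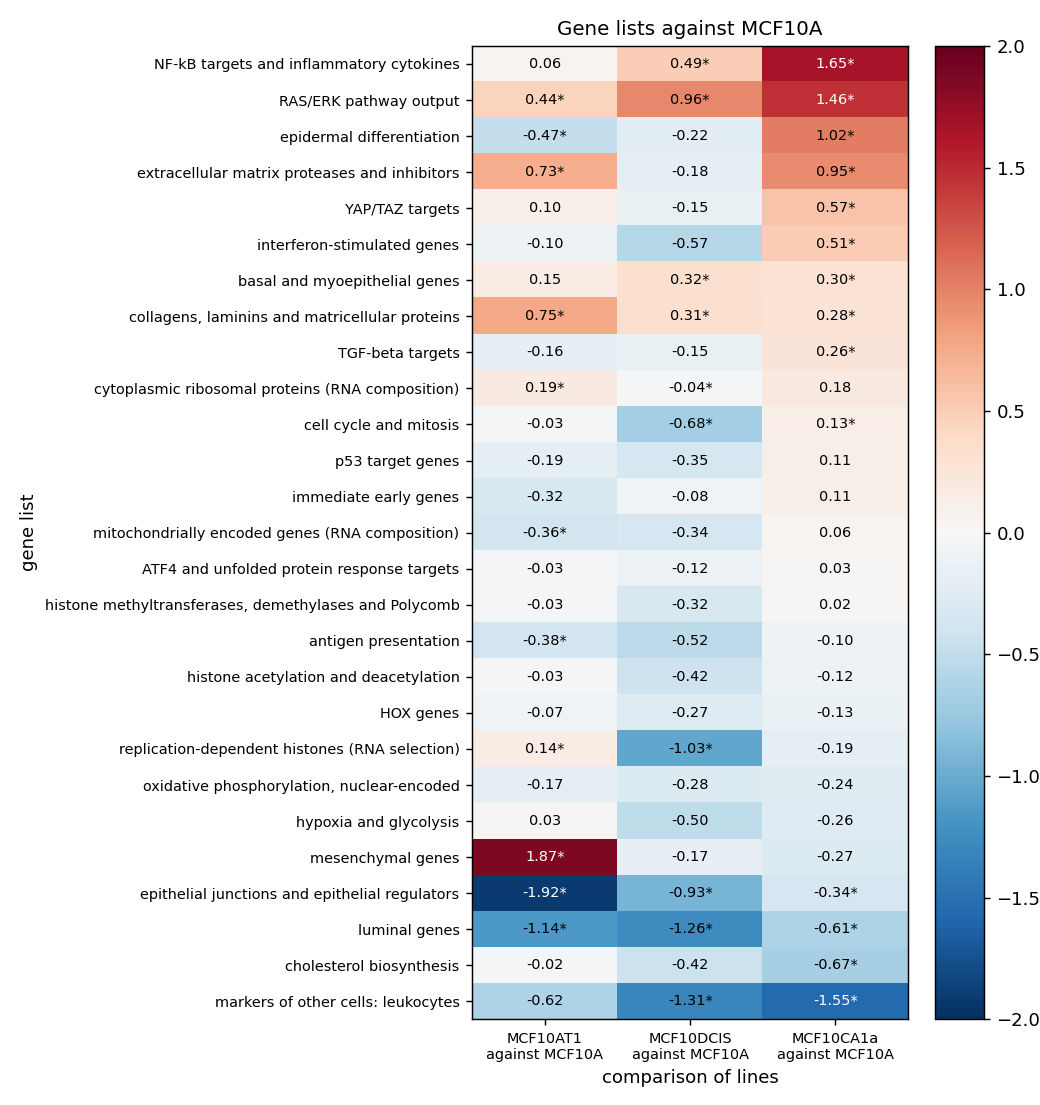
Median log2(TPM + 1) difference from MCF10A of the 27 gene lists with at least 5 measured members in the 3 derived lines, in red where higher and blue where lower, with an asterisk where the median lay among the highest or lowest 2.5% of 10000 matched random lists. The RAS/ERK output list was 0.44, 0.96 and 1.46 and the mesenchymal list 1.87, -0.17 and -0.27 in MCF10AT1, MCF10DCIS and MCF10CA1a.

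Lists that stood neither above nor below in any of the 3 comparisons with MCF10A included those of chromatin regulators. Histone methyltransferases, demethylases and Polycomb genes had medians of -0.030, -0.32 and 0.023 in MCF10AT1, MCF10DCIS and MCF10CA1a, with percentiles of 79.8, 87.6 and 90.1. In MCF10DCIS 5 of these 43 genes were lower, or 2 with rescaled TPM. Among them were the H3K4 methyltransferase gene KMT2C with a difference of -2.02 and the H3K27 methyltransferase gene EZH2 at 13.8 TPM in MCF10A and 4.22 TPM in MCF10DCIS. Both lie on chromosome 7, whose genes as a whole were lower in MCF10DCIS, with a median of -0.63 relative to other autosomes on the rescaled scale. On that scale KMT2C differed by -1.93 and EZH2 by -1.29. Histone acetylation and deacetylation genes had medians of -0.031, -0.42 and -0.12, and HOX genes -0.069, -0.27 and -0.13. The medians of p53 targets were -0.19, -0.35 and 0.11, of immediate early genes -0.32, -0.076 and 0.11, of hypoxia and glycolysis genes 0.027, -0.50 and -0.26, of ATF4 and unfolded protein response targets -0.030, -0.12 and 0.027, and of nuclear-encoded oxidative phosphorylation genes -0.17, -0.28 and -0.24. With rescaled TPM the medians of these 8 lists were higher and none of the lists stood above or below. In MCF10DCIS those of methyltransferase, immediate early, ATF4 target and oxidative phosphorylation genes were then above 0 (0.034, 0.29, 0.23 and 0.088), and in MCF10AT1 those of methyltransferase, acetylation, HOX and ATF4 target genes (0.085, 0.077, 0.028 and 0.088). The angiogenic factor gene VEGFA was 75.7 TPM in MCF10A and 27.4, 26.9 and 17.3 TPM in the derived lines. Of 22 cancer-testis antigen genes 0 reached 1 TPM in any line. Endothelial markers were measured for 3 of 12 genes and adipocyte markers for 4 of 8, too few for a percentile. Among the adipocyte markers, FABP4 was 0.0179 TPM in MCF10A and 3.49 TPM in MCF10CA1a, and PLIN4 0.763 and 4.51 TPM. The remaining members are not given here.

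MCF10DCIS and MCF10AT1, neighbours in the order of the stages, were compared next. Mesenchymal genes were lower and epithelial junction genes higher in MCF10DCIS than in MCF10AT1. Of 16 mesenchymal genes 14 were lower in MCF10DCIS and 1 higher (median -2.12, percentile 0), with DCN at 134 TPM in MCF10AT1 and 0.142 TPM in MCF10DCIS and FN1 at 303 and 2.01 TPM. Epithelial junction genes had 11 of 24 higher, or 15 with rescaled TPM, and 0 lower (median 0.93, percentile 100), with the small GTPase gene RAB25 at 23.5 and 113 TPM and the claudin gene CLDN1 at 4.08 and 21.3 TPM. CDH1 differed by 0.96, and by 1.22 to 1.32 under the 3 other scalings, and VIM by -1.27, or -0.90 with median-of-ratios scaling, below the rule of size. The inflammatory list had 12 of 23 higher and 0 lower (median 1.44, percentile 100). RAS/ERK outputs had 6 of 22 higher, or 10 with rescaled TPM, and 0 lower (median 0.57, percentile 100). Basal and myoepithelial genes had 5 of 19 higher and 2 lower (median 0.37, or 0.61 with rescaled TPM, percentile 100). EREG, an EGF receptor ligand, was 2.67 and 25.6 TPM and KRT17 227 and 971 TPM. Epidermal differentiation (median 0.16), luminal (0.23), immediate early (0.28) and ATF4 target (-0.045) lists also stood above matched genes, with medians of 0.42, 0.48, 0.52 and 0.19 with rescaled TPM. The immediate early list had a mean of -0.052 against its median of 0.28, and the ATF4 target list had 0 of 22 genes higher, or 2 with rescaled TPM, and 2 lower.

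Matrix proteases and inhibitors were lower in MCF10DCIS than in MCF10AT1 (7 of 16 lower, 1 higher, median -0.85, percentile 0), with TIMP1 at 504 and 121 TPM. Cell cycle genes (5 of 34 lower, or 2 with rescaled TPM, 0 higher, median -0.68), replication-dependent histones (22 of 35 lower, or 16 with rescaled TPM, 0 higher, median -1.16) and interferon-stimulated genes (6 of 26 lower, 3 higher, median -0.62) stood below matched lists. TGF-beta targets did so with the deposited TPM (percentile 1.8) and not with rescaled TPM (percentile 3.9). The largest single differences were those of SPARC (5.40), LEMD1 (5.13), BST2 (5.10) and S100A1 (4.96) upward and DCN (-6.88), FN1 (-6.66), TGFBI (-6.24) and FLNA (-6.22) downward. FLNA, which encodes the actin crosslinker filamin A, was 236 TPM in MCF10AT1 and 2.18 TPM in MCF10DCIS. KRT5 differed by 0.12, KRT14 by -1.75 and TP63 by 0.31. In all, 424 genes were higher and 985 lower (30.1% higher), or 851 and 964 (46.9% higher) with rescaled TPM and 771 and 539 (58.9% higher) with median-of-ratios scaling. Of the lists 8 stood above and 6 below.

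MCF10CA1a was compared with MCF10DCIS, the line before it in the order of the stages. Whether MCF10CA1a descends from MCF10DCIS was not examined, so a difference may belong to either line. As described below, genes of chromosome 9 were higher as a whole in MCF10AT1 and MCF10CA1a but not in MCF10DCIS. Chromosomes 15 and 20 differed too, with medians of 0.39 and -0.42 in MCF10DCIS and -0.068 and 0.12 in MCF10CA1a. Genes of parts of chromosomes 2 and 3, by contrast, were higher in both MCF10DCIS and MCF10CA1a but not in MCF10AT1. Inflammatory genes (13 of 23 higher, 1 lower, or 3 with rescaled TPM, median 1.19), interferon-stimulated genes (13 of 26 higher, 1 lower, median 0.98), matrix proteases and inhibitors (6 of 16 higher, 0 lower, median 0.90) and cell cycle genes (11 of 34 higher, 0 lower, median 0.76) were higher in MCF10CA1a, each at percentile 100. IL1B was 9.44 TPM in MCF10DCIS and 135 TPM in MCF10CA1a, the urokinase gene PLAU 7.07 and 117 TPM, and the topoisomerase gene TOP2A 16.4 and 52.2 TPM. The antimicrobial protein gene LCN2 differed by 3.24 and the antiviral enzyme gene OAS1 by 2.59. Epidermal differentiation (median 0.67, percentile 99.9), epithelial junction (0.59, 99.9), TGF-beta target (0.57, 99.5), RAS/ERK output (0.51, 98.5) and replication-dependent histone genes (0.73, 100) also stood above matched lists. The histone genes had 8 of 35 higher and 2 lower, or 2 and 2 with rescaled TPM, and a mean of 0.38. Epithelial junction genes had 3 of 24 higher and 0 lower, or 2 higher and a median of 0.38 with rescaled TPM. Cholesterol biosynthesis genes stood below (median -0.30, percentile 0), as did mesenchymal (-0.076, 0.08), basal and myoepithelial (-0.020, 0.02) and oxidative phosphorylation genes (0.11, 0.39), the last with a median above 0 but below the median of 0.30 of all genes in this comparison. With rescaled TPM the medians of these 4 lists were -0.53, -0.28, -0.24 and -0.12, that of RAS/ERK outputs was 0.31, and collagens, laminins and matricellular proteins stood below as well (percentile 2.46, against 2.67 with the deposited TPM).

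Among single genes KRT13 (5.45), SERPINB2 (4.34), ANXA10 (4.05) and TMPRSS15 (3.97) differed most upward from MCF10DCIS to MCF10CA1a, and KRT81 (-6.82), H1-5 (-6.06), the lipoprotein lipase inhibitor gene ANGPTL4 (-5.65) and S100A1 (-4.75) most downward. KRT5 differed by -2.34, VIM by -1.51, KRT14 by -0.41 and TP63 by 0.69. CDH1 differed by 0.29 with the deposited TPM and by -0.018 and -0.072 with quantile normalization and median-of-ratios scaling. In all, 790 genes were higher and 177 lower, 81.7% on the higher side. That share was 67.6% with rescaled TPM (777 and 373 genes) and 53.5% with median-of-ratios scaling (387 and 337 genes). Of the lists 9 stood above and 4 below, and all 13 kept their direction with rescaled TPM.

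MCF10CA1a and MCF10AT1 were compared across the intermediate stage. The inflammatory list had 19 of 23 genes higher in MCF10CA1a and 0 lower (median 1.77), epithelial junction genes 19 of 24 higher and 0 lower (median 1.35), and epidermal differentiation genes 11 of 17 higher and 2 lower, each of the 3 at percentile 100. RAS/ERK outputs (0.89), basal and myoepithelial genes (0.71), interferon-stimulated genes (0.61), luminal genes (0.55), p53 targets (0.21), cell cycle genes (0.20) and mitochondrially encoded genes (0.28) stood above matched lists as well. RAS/ERK outputs had 10 of 22 genes higher and 1 lower, but p53 targets had 1 of 20 higher and 1 lower (percentile 98.0). Cell cycle genes had 2 of 34 higher and mitochondrially encoded genes 0 of 13. Luminal genes had 3 of 11 higher, 1 lower and a mean of 0.18. Mesenchymal genes had 13 of 16 lower and 1 higher (median -2.62), and replication-dependent histones (-0.44), cholesterol biosynthesis genes (-0.53), hypoxia and glycolysis genes (-0.34), collagens and matricellular proteins (-0.25) and leukocyte markers (-0.93, or -1.60 with rescaled TPM) also stood below. The elafin gene PI3 (6.53), GPX2 (6.25), LCN2 (5.97) and CXCL8 (5.97) had the largest upward differences, and H1-5 (-7.12), DCN (-6.90), the core histone gene H3C1 (-6.55) and FN1 (-5.96) the largest downward. LCN2 was 1.42 TPM in MCF10AT1 and 150 TPM in MCF10CA1a. HRAS differed by 1.30, CDH1 by 1.25, VIM by -2.78, KRT5 by -2.22, KRT14 by -2.16 and TP63 by 1.01, the last below the rule of size with quantile normalization (0.97) and with median-of-ratios scaling (0.9999). In all, 786 genes were higher and 520 lower, or 1077 and 704 with rescaled TPM, and 10 lists stood above and 6 below.

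By the number of genes past the rule of size, MCF10CA1a and MCF10DCIS were the closest pair, with 967 genes, and MCF10DCIS and MCF10A the farthest, with 2404. With rescaled TPM the same pairs were closest and farthest, with 1150 and 2345 genes. Genes past the rule of size against MCF10A in all 3 derived lines numbered 124 on the higher side and 367 on the lower, where independent lists of these sizes would share 0.945 and 8.13. With rescaled TPM they numbered 279 and 369, against 5.53 and 6.93 for independent lists. HRAS, VIM, TP63, PLAT, FKBP10 and PTPRS were among the first and CYBA, WFDC2, AZGP1, NCCRP1, KLK7, KLK8, ELF3, CD24, CDH1 and KRT14 among the second. As described below, genes of chromosomes 7, 8 and 16 were lower as a whole in all 3 derived lines. Independent lists are therefore not a fair expectation, at least on the lower side. Part of the overlap may also come from the MCF10A libraries, which all 3 comparisons share. The simulation of unchanged groups that would measure it needs the spread between libraries and was not possible on means. MCF10DCIS and MCF10CA1a had 193 higher and 396 lower genes in common that were not past the rule in MCF10AT1, or 378 and 335 with rescaled TPM. MCF10AT1 had 235 higher and 213 lower genes that neither of the others shared, or 274 and 284 with rescaled TPM.

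Genes that stepped in 1 direction along the order MCF10A, MCF10AT1, MCF10DCIS, MCF10CA1a numbered 95 upward and 60 downward. PLAT, IL1B, CXCL8, FKBP10 and UGT1A6 had the largest total differences upward, with CXCL8 at 1.31, 2.02, 25.5 and 188 TPM along the order. H1-5, WFDC2, MUC1, the sodium channel subunit gene SCNN1B and SECTM1 had the largest downward, with MUC1 at 123, 55.1, 11.2 and 0.438 TPM. The total of 155 genes was not the highest of the 12 possible orders. The order with MCF10CA1a before MCF10DCIS gave 265 genes (28 upward, 237 downward), and the other 10 orders gave 34 to 110. With rescaled TPM the order of the design gave 250 genes and the order with these 2 lines exchanged 246.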

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

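No paired analysis was possible because the deposited columns are means per line and carry no replicate numbers. For the same reason the alternatives that need libraries were not run: leaving out each library, the replicate block, fits on 2 lines, a constant or robust prior, adjusted p alone, an estimated correlation between list members, and fry. No alternative tried turned the direction of a named gene that was past the rule of size. Of 267 differences of named genes, 251 stayed on their side of the rule with quantile normalization, 247 with median-of-ratios scaling and 256 of 265 with rescaled TPM, and all did so with a pseudocount of 0.1 and with no filter, as did the 249 that a filter of 5 TPM left. The depth is unknown, so what it limits cannot be given.

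A pseudocount of 0.1 raised counts by its construction, since low genes are shrunk less. It gave 758 higher and 1211 lower genes for MCF10AT1 against MCF10A, 768 higher for MCF10DCIS against MCF10A, 720 and 1767 for MCF10DCIS against MCF10AT1, 1468 and 327 for MCF10CA1a against MCF10DCIS, and 1199 and 816 for MCF10CA1a against MCF10AT1. It also gave 298 higher and 568 lower genes in all 3 derived lines and 170 upward and 118 downward along the order. A filter of 5 TPM, which leaves fewer genes, gave 275, 310 and 514 higher genes for MCF10AT1, MCF10DCIS and MCF10CA1a against MCF10A, 117 lower for MCF10CA1a against MCF10DCIS, and 2 lists below for MCF10CA1a against MCF10A. Without a filter, 3 lists stood below for MCF10DCIS against MCF10A; the cause was not tested.

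Scalings that centre the lines on each other moved the counts that involve MCF10DCIS, whose median lay at -0.38 from MCF10A as deposited. Quantile normalization gave 848 higher and 814 lower genes for MCF10DCIS against MCF10A, 722 and 566 against MCF10AT1, and 373 and 342 for MCF10CA1a against MCF10DCIS. Median-of-ratios scaling gave 846 and 845, 771 and 539, and 387 and 337 for the same pairs. Rescaled TPM gave 749, 1009 and 1219 higher genes for MCF10AT1, MCF10DCIS and MCF10CA1a against MCF10A, 851 higher for MCF10DCIS against MCF10AT1, 373 lower for MCF10CA1a against MCF10DCIS, 279 higher in all 3 derived lines, and 152 upward and 98 downward along the order. Rescaled values are also larger, so that the pseudocount weighs less. The HRAS difference between MCF10CA1a and MCF10DCIS was -0.083 with quantile normalization, -0.19 with median-of-ratios scaling and -0.051 with rescaled TPM.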

Other observations

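The patterns in this part were chosen after the values were seen, and so were all tests except those on GC content with transcript length and on SRF target genes; for the latter, the values of ACTA2 and TAGLN had been seen and the median of the set had not. Chromosomes 7, 8 and 16 were picked from 23 chromosomes in 3 lines, and the limits for a copy number explanation were set after their medians were seen. A few genes were at 10 TPM or more in some lines and below 0.5 TPM in the others. MCF10A alone expressed 5 such genes: CYBA, the mitochondrial respiratory subunit gene COX7A1 (42.7 TPM), the acyltransferase gene GPAT2 (24.8 TPM), the epidermal protease gene CASP14 (15.8 TPM) and the histone gene H4C13 (10.9 TPM). MCF10AT1 alone expressed DCN and the monoamine oxidase gene MAOA (11.1 TPM). MCF10DCIS alone expressed S100A1 (31.2 TPM) and the cyclin gene CCND2 (13.9 TPM), and MCF10CA1a alone KRT13, ANXA10 (16.2 TPM) and CALML3 (13.5 TPM). MCF10DCIS and MCF10CA1a shared NGFR, GPX2, the serine protease gene PRSS21 (21.6 TPM in both) and the cytidine deaminase gene APOBEC3G (10.5 and 13.4 TPM). MCF10A and MCF10AT1 shared EMD, MSLN, VSTM2L, TOR4A and the transcription factor gene ZBTB16 (11.1 and 13.2 TPM). MYADM, a membrane protein gene, was at 38.9, 14.7 and 15.1 TPM in MCF10A, MCF10AT1 and MCF10CA1a and at 0.0396 TPM in MCF10DCIS.

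Over 9420 protein-coding genes with a mean log2 value of at least 3, the median log2 difference from MCF10A relative to the other autosomes, on the rescaled scale, was -0.52, -0.63 and -0.60 in MCF10AT1, MCF10DCIS and MCF10CA1a for chromosome 7, -0.53, -0.59 and -0.55 for chromosome 8, and -0.49, -0.56 and -0.61 for chromosome 16. GC content or transcript length is argued against, since the highest of the 9 medians was -0.53 after each gene was matched to 20 genes of other autosomes on GC content, transcript length and level. The lowest of the 9 shares of genes below the median of the other autosomes was 86.9%, which describes the same displacement and is no separate test of it. A candidate explanation is 2 copies in the derived lines where these MCF10A cells carry 3, with a log2 ratio of -0.58: the largest distance of the 9 medians from it was 0.092, and the highest median on either side of the middle gene of these chromosomes was -0.45. DNA copy number was not analysed here, so this stays a hypothesis. Named genes on these chromosomes were not corrected for the displacement, among them EZH2, KMT2C and CYP51A1 on chromosome 7, CCNE2 on chromosome 8 and CDH1 and MVD on chromosome 16.

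Other chromosomes were displaced as well. Chromosome 9 had a median of 0.54 in MCF10AT1, -0.024 in MCF10DCIS and 0.54 in MCF10CA1a. Chromosome 10 had 0.10, 0.35 and 0.33, chromosome 20 had -0.16, -0.42 and 0.12, chromosome 15 0.011, 0.39 and -0.068, and chromosome 18 -0.29, -0.37 and -0.27. On some chromosomes the displacement differed between the genes before and after the middle gene: the genes before the middle gene of chromosome 2 had medians of 0.48 in MCF10DCIS and 0.51 in MCF10CA1a against -0.031 and -0.0037 for those after it, and the genes after the middle gene of chromosome 3 had 0.52 and 0.54 against 0.079 and 0.044. In MCF10DCIS the medians before and after it were -0.039 and 0.45 on chromosome 1, 0.27 and -0.034 on chromosome 14, and 0.093 and 0.51 on chromosome 17. In windows of 30 genes, a stretch of chromosome 17 from 17246820 to 21193265 (GRCh38) had medians of 1.05, 0.74 and 0.88 in MCF10AT1, MCF10DCIS and MCF10CA1a.

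FLNA and EMD, neighbours on chromosome X from 154348524 to 154381523 (GRCh38), were lower in MCF10DCIS and MCF10CA1a: EMD, which encodes the nuclear envelope protein emerin, was 24.5 TPM in MCF10A, 28.9 TPM in MCF10AT1, 0.0750 TPM in MCF10DCIS and 0.0538 TPM in MCF10CA1a, and FLNA was 132, 236, 2.18 and 3.47 TPM. Lower output of SRF targets of the actin cytoskeleton is argued against by 24 other such genes, whose lower median was -0.12 and whose lowest value was -1.60 on the rescaled log2 scale, where FLNA differed by -5.39 and -4.98. Of the 20 nearest expressed genes outside the ribosomal protein genes, 17 were within 1 log2 unit of MCF10A in both lines, and RPL10, directly beyond EMD, was 1028 TPM in MCF10A, 970 TPM in MCF10DCIS and 1113 TPM in MCF10CA1a. A short DNA loss holding both genes stays open. The neighbours leave room for it, but FLNA remained above 1 TPM in both lines. The source of those reads was not examined, so they cannot decide whether the whole gene was lost. Loss of reads in alignment or counting stays open too, since the genes were picked for their level in MCF10A and MCF10AT1 and its lowest value of 24.5 TPM decides nothing, and silencing was not tested.

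The mesenchymal genes that were high in MCF10AT1, DCN and FN1 in that line alone and VIM also, at lower levels, in MCF10DCIS and MCF10CA1a, raise the question of other cells in those cultures. Fibroblasts are argued against as the main source of DCN. The highest of COL1A1, COL1A2 and COL3A1, abundant transcripts of such cells, reached 0.0240 of the level of DCN in MCF10AT1. PDGFRA, LUM and THY1 were below 0.1 TPM there, and PDGFRB was 0.154 TPM. DCN was picked for its level in MCF10AT1, so if epithelial cells express it the ratio cannot exclude a small part of fibroblasts. COL1A1 was 0.674 TPM in MCF10A and 3.22, 2.78 and 2.58 TPM in MCF10AT1, MCF10DCIS and MCF10CA1a. Another fibroblast marker, FAP, was 15.8 TPM in MCF10A and 7.85 TPM in MCF10AT1. KRT5 was 592 TPM in MCF10AT1 and 768 TPM in MCF10A, but other basal keratin genes were lower in MCF10AT1. KRT15 was 395 TPM in MCF10AT1 and 2830.4 TPM in MCF10A, and KRT14 24.6 and 57.8 TPM. Of 19 basal and myoepithelial genes, 2 were higher and 4 lower in MCF10AT1 by the rule of size. A shift within the epithelial cells of this line may account for the pattern. Whether all cells or a part of them carry it stays open in bulk RNA, and HRAS transformation, which the design names, cannot be separated from the history of the line with 1 line per stage.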
